A study of Mus musculus with 32 samples.

How the data were processed

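RNA of uteri from female CD-1 mice on postnatal day 5 was measured on 32 single-colour Agilent mouse arrays, with 1 array per sample. Per the labels, total RNA was labelled with Cy3, and each of the 8 groups held 4 biological replicates. The groups were vehicle and DES in Esr1 wild-type and cKO mice, and DES in Foxa2 wild-type and cKO and in Foxo1 wild-type and cKO mice. The sources used here give no DES dose, Cre driver, litter, slide or hybridization date. The replicate numbers were not taken as pairs, and each sample counted as independent.

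The authors deposited an intensity for each probe on each array, extracted with Agilent Feature Extraction 12 per the submitters' processing notes. Background correction and normalization of these values are not given in the sources used here. The values ran from 1.8712 to 922772 on a linear scale, with array 75th percentiles from 551 to 9024, so they were not on a common scale between arrays. Of the 45018 probes in the table, 33653 carried 1 gene symbol, 56 several and 11309 none, and symbols were brought up to date through gene IDs for 33517. Only probes with 1 symbol entered the gene tests. Probes without a symbol were tested apart for the count given in the closing section.

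Values were put on the log2 scale and the 75th percentile of each array was subtracted. A probe was kept if it lay above its array's 30th percentile in at least 4 of the 32 arrays, which left 36657 probes. A gene was represented by its kept probe with the highest mean over all arrays, which gave 17145 genes. The level of a gene is this log2 value. A gene whose arrays in one group all lay under their array's 30th percentile counts as dim there. Its change is given as a bound, the distance of the other group's mean from that percentile, written "at least" where positive and "bound" where negative. A difference between effects is bounded likewise, with dim groups set to that percentile, and is not given where a dim group leaves no bound.

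Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 32 arrays (24 residual degrees of freedom), a moderated t test and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05. Differences between effects were tested as contrasts of contrasts. All p-values of single genes are from limma, and those of lists from camera or fry of the same package. 22 lists of genes were fixed from general knowledge: estrogen-responsive uterine genes, epithelial secretory and innate-defence genes, Müllerian duct patterning genes, gland genes, stratified and basal epithelial genes, simple epithelial genes, stromal fibroblast genes, smooth muscle genes, proliferation genes, leukocyte genes, endothelial genes, red blood cell genes, ovary and oocyte genes, mesothelial genes, adipocyte genes, skeletal muscle genes, FOXO-regulated genes, steroid and nuclear receptors, retinoid metabolism genes, growth factors and IGF axis genes, ion and water transport genes, and histone-modifying enzymes. They were tested with camera at an inter-gene correlation of 0.01, adjusted over the 22 lists of a comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

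Genes changed at least 2-fold by DES in Esr1 wild type formed a raised and a lowered list, tested in the comparisons that share no array with them. For the Esr1 genotype comparisons, the lists were made from replicates 1 and 2 of the shared group and tested on its replicates 3 and 4. Where 1 of these was left out, the remaining array was assumed to vary like the other groups. The named genes are Esr1, Foxa2 and Foxo1, up to 8 genes per direction with the largest fitted change among calls without overlap between the 4 and 4 arrays, taken from the top of that order, and up to 4 called members of each list with the largest change. Where no member was called, the member with the largest value is given. Gene models without an established name were left out. A gene named in one comparison may be given in others. Cdh1 between the wild-type groups, Ifi202b, Xist, Slc7a11 and Shisa2 fall outside this rule and were chosen after their values were seen. The groups, the 22 lists, the tests and the naming rule were fixed before the data were examined. The bound for dim genes and the list of interferon-inducible genes in the closing section were added later.

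The alternatives were quantile normalization, median scaling, adding 16 to each value, no probe filter or a filter at the array median, the mean of a gene's probes or all probes, only the compared groups in the fit, another variance model, array weights, replicate number as a block, an adjusted p under 0.01, a 2-fold minimum and leaving out each array in turn. Leaving out both doubted arrays, and the division of the Foxa2 and Foxo1 lines into replicates 1 and 2 and replicates 3 and 4, were chosen after the data were seen. The fit was tested on simulated data in which 250 genes per size were changed, in 5 simulations. At log2 changes of 0.5, 1, 2 and 3 it recovered 10.0%, 48.8%, 88.8% and 95.6% of them, and 5.0% of calls were false. The simulated values were normal and independent between genes, with 1 spread per gene over all groups and no deviating arrays or sets of replicates. Recovery and false calls in the real data may therefore differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.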

Results

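Gene expression was measured in uteri of female CD-1 mice on postnatal day 5, with 1 single-colour Agilent array of Cy3-labelled RNA per sample. The 32 arrays formed 8 groups of 4, which the series design calls biological replicates. In the Esr1 line, wild-type and conditional knockout (cKO) uteri were taken after vehicle or after diethylstilbestrol (DES), a synthetic estrogen. In the Foxa2 and Foxo1 lines, wild-type and cKO uteri were taken after DES, and no vehicle-treated uteri of these lines were analysed here. Esr1 encodes estrogen receptor alpha, and Foxa2 and Foxo1 encode forkhead transcription factors. Foxa2 is known from uterine gland epithelium. The comparisons ask how deletion of each gene alters expression under DES, and in the Esr1 line also how the response to DES itself is altered. The 75th percentile of the deposited intensities lay between 697 and 1787 on all arrays except a pair. It was 9024 on replicate 1 of the DES-treated Foxa2 wild-type group and 551 on replicate 4 of the vehicle-treated Esr1 wild-type group. On the latter array the level of Xist, the RNA of the inactive X chromosome, was -2.35, against 3.56 to 4.02 on the other 3 arrays of its group. These are called the doubted arrays, and the total of called genes in each comparison is also given without them. Levels are log2 values minus the array's 75th percentile. Changes are log2 fold changes ± SE from limma, with 4 arrays per group, and a gene was called at an adjusted p under 0.05. The number of arrays limits the precision.

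The targeted genes were examined first, in every sample. After DES, the Esr1 level was 0.27 ± 0.15 (SD, n = 4) in Esr1 cKO uteri and 2.23 ± 0.10 (SD, n = 4) in wild type, and the arrays of both groups did not overlap (0.09 to 0.46 against 2.12 to 2.35). The difference was -1.96 ± 0.40 (adjusted p = 3.9e-04), which left 25.8% of the wild-type level. After vehicle, the Esr1 level was 2.55 ± 0.18 (SD, n = 4) in cKO and 3.29 ± 0.80 (SD, n = 4) in wild type. The arrays overlapped, and the difference of -0.74 ± 0.40 did not pass the test (adjusted p = 0.330). It was -0.36 without wild-type replicate 4 (adjusted p = 0.0978 without the doubted arrays), and array weights alone gave a call (-0.41, adjusted p = 0.0277). Foxa2 was -0.11 ± 0.31 (SD, n = 4) in Foxa2 cKO and 2.87 ± 0.95 (SD, n = 4) in its wild type, with arrays at -0.29 to 0.36 and 1.47 to 3.58, a difference of -2.99 ± 0.40 (adjusted p = 4.5e-05) that left 12.6%. Foxo1 was 1.23 ± 0.11 (SD, n = 4) in Foxo1 cKO and 3.87 ± 0.17 (SD, n = 4) in its wild type, with arrays at 1.12 to 1.33 and 3.68 to 4.06, a difference of -2.64 ± 0.19 (adjusted p = 1.0e-09) that left 16.1%. The position of the probes relative to the deleted part of each gene was not known, so a remaining signal may include transcript outside it.

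**Figure D1:**
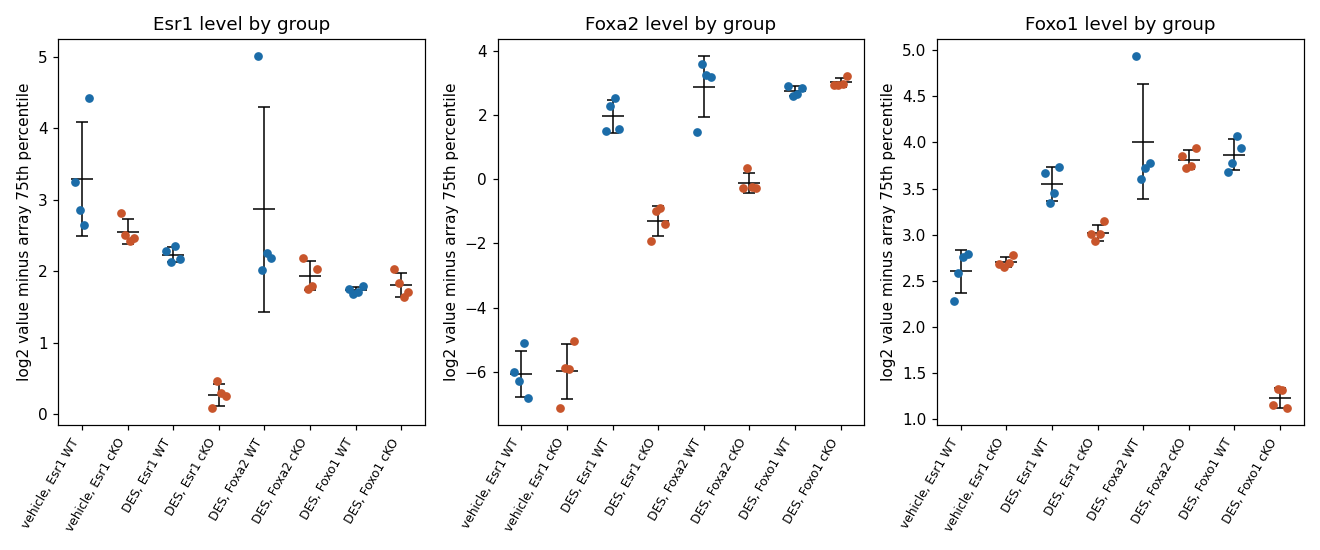
Level of Esr1, Foxa2 and Foxo1 (log2 value minus the array 75th percentile) on each of the 32 arrays, in 8 groups of 4, with the group mean and SD as bars and cKO groups in orange. Each targeted gene was lowest in its own DES-treated cKO group among the DES-treated groups, except Foxa2, which was lower in the Esr1 cKO group (-1.30 ± 0.47) than in the Foxa2 cKO group (-0.11 ± 0.31).

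The targeted genes also responded to DES and to loss of Esr1. Foxa2 had a low signal in vehicle-treated uteri of the Esr1 line, at -6.06 ± 0.72 (SD, n = 4) in wild type and -5.99 ± 0.86 (SD, n = 4) in cKO. It rose with DES by 8.02 ± 0.40 in wild type (adjusted p = 2.3e-15) and by 4.69 ± 0.40 in Esr1 cKO (adjusted p = 1.5e-09), with a difference of -3.33 ± 0.57 (adjusted p = 7.6e-05). Over the 10 probes of Foxa2 the rise was 7.61 to 8.73 in wild type and 4.69 to 6.89 in cKO, and the difference -3.83 to -0.77. The vehicle signal lay near the floor, so the sizes of these changes are uncertain. After DES, cKO minus wild type was -3.45 to -3.20 over the same probes. Foxo1 rose with DES by 0.95 ± 0.19 in wild type (adjusted p = 1.3e-04). In Esr1 cKO its value was 0.32 ± 0.19 (adjusted p = 0.393), a call with quantile normalization, only the compared groups in the fit, array weights or without the doubted arrays (adjusted p = 0.0333, 0.0169, 0.007 and 0.0283). The test of the difference gave an adjusted p of 0.0785. The difference was called with the same settings (adjusted p = 0.0091, 0.0133, 1.2e-04 and 7.2e-04 in that order). Esr1 fell with DES by 1.06 ± 0.40 in wild type (adjusted p = 0.0285; 11 of 11 probes in that direction) and by 2.28 ± 0.40 in Esr1 cKO (adjusted p = 2.2e-04). The wild-type call of Esr1 was lost without vehicle wild-type replicate 4 (-0.69, adjusted p = 0.157), without DES wild-type replicate 2 (adjusted p = 0.0581) or replicate 4 (adjusted p = 0.0533), and with median scaling (-0.82, adjusted p = 0.124). The difference between the Esr1 genotypes was -1.22 ± 0.57 (adjusted p = 0.116), or -1.59 (adjusted p = 2.2e-07) without the doubted arrays. It was also called with quantile normalization, the mean of probes, only the compared groups in the fit or array weights (adjusted p = 0.0037, 0.043, 0.0261 and 9.95e-08). Leaving out vehicle wild-type replicate 4 alone gave a call too (adjusted p = 0.03), and the other alternatives examined for it gave none.

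In Esr1 wild-type uteri, DES raised genes of secretion, innate defence and transport and lowered genes of duct patterning. The largest fitted rises were those of Lcn2, a siderophore-binding defence protein (10.92 ± 0.46, adjusted p = 6.2e-17), Unc5cl, dim on all vehicle arrays (at least 9.62), and Aoc1, a histamine-degrading oxidase (10.49 ± 0.44). Ltf, which encodes lactoferrin, rose by 9.93 ± 0.35, Arg1, an arginase, by 9.87 ± 0.34, Aqp8, a water channel, by 9.85 ± 0.46, and Uox, urate oxidase, by 9.54 ± 0.25. The largest fitted falls were those of Slc6a2, the noradrenaline transporter (bound -7.12), Vwa2, a matrix protein (bound -6.80), and Lgr5, an R-spondin receptor (-7.26 ± 0.39, adjusted p = 9.2e-15). Camkv (bound -5.47), G6pc2, a glucose-6-phosphatase subunit (-6.41 ± 0.40), and Mmp10, a matrix metalloproteinase (-6.20 ± 0.42), followed.

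Estrogen-responsive uterine genes rose as a list, with 22 of 27 measured members higher, 2 lower and 3 not called, and 22 and 2 when adjusted over the list alone (median 3.35, camera adjusted p = 3.0e-15). Besides Lcn2, Ltf and Aqp8, Clca1, a regulator of calcium-activated chloride channels, rose by 9.21 ± 0.40. Uterine epithelial secretory and innate-defence genes rose in 14 of 20 and fell in 3 (16 and 3 adjusted over the list alone; median 2.77, adjusted p = 3.9e-08), among them Pigr, the polymeric immunoglobulin receptor (at least 4.93), and Chil1, a chitinase-like protein (6.26 ± 0.31). Ion and water transport genes rose in 12 and fell in 5 of 23, the same counts adjusted over the list alone (median 1.43, adjusted p = 5.9e-04), including Car12, a carbonic anhydrase (6.52 ± 0.35), and Atp6v0a4, a proton pump subunit (4.87 ± 0.37). Müllerian duct patterning genes, which shape the embryonic female tract, fell in 18 and rose in 6 of 30 (19 and 6 adjusted over the list alone; median -1.48, adjusted p = 0.0018). The Wnt pathway members Lef1 (-5.70 ± 0.33), Wnt7a (-3.74 ± 0.30), Wnt11 (-3.33 ± 0.33) and Axin2 (-2.85 ± 0.35) fell most. These 4 lists kept their call with an estimated correlation (adjusted p = 3.7e-05, 0.0048, 0.0188 and 0.0188 in that order).

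4 more lists were called with the preset but not the estimated correlation. All 8 lists called with the preset correlation kept their call with fry. Of the 29 measured proliferation genes, 28 fell and 1 was not called, likewise adjusted over the list alone (median -1.32, adjusted p = 1.9e-07, and adjusted p = 0.272 with an estimated correlation). The replication helicase subunit Mcm3 (-1.94 ± 0.38) and the cell cycle transcription factor E2f1 (-1.79 ± 0.27) fell most. Simple epithelial genes rose in 21 and fell in 2 of 24, likewise over the list alone (median 1.53, adjusted p = 5.5e-08, and 0.0803 with an estimated correlation). The epithelial regulators Elf3 (3.87 ± 0.39) and Ovol2 (3.72 ± 0.40) rose, and the tight junction gene Cldn6 (-5.59 ± 0.30) fell. Leukocyte genes rose in 14 and fell in 5 of 22 (14 and 6 adjusted over the list alone; median 1.14, adjusted p = 0.0037, and 0.272 with an estimated correlation), with the integrin Itgam (6.50 ± 0.46) and the endotoxin co-receptor Cd14 (2.28 ± 0.21) highest. Smooth muscle genes fell in 12 and rose in 1 of 17, likewise over the list alone (median -0.72, adjusted p = 0.0037, and 0.272 with an estimated correlation). Myocd, a smooth muscle transcriptional coactivator, fell by 2.44 ± 0.21, and Ldb3 by 2.32 ± 0.65, a call lost when its probes were averaged (-0.16, adjusted p = 0.734).

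The remaining lists were not called with DES in wild type, although single members changed strongly. Of the 14 gland genes 6 rose and 6 fell, likewise adjusted over the list alone. Besides the rise of Foxa2 and the fall of Lgr5, the chemokine gene Cxcl15 rose by at least 2.95. The list had a median of -0.66 but a mean of 0.20 (adjusted p = 0.708). Stratified and basal epithelial genes rose in 8 and fell in 6 of 26, likewise over the list alone (median -0.09, mean 0.32, adjusted p = 0.367), with Calml3 higher (6.13 ± 0.40) and Krt17 (-4.84 ± 0.63) and the basal cell factor Trp63 (-3.68 ± 0.28) lower. FOXO-regulated genes rose in 9 and fell in 6 of 28 (9 and 7 adjusted over the list alone; median 0.08, adjusted p = 0.0874). Pck1, which encodes the gluconeogenic enzyme PEPCK, rose by 7.04 ± 0.88 and the stress response gene Gadd45a by 4.60 ± 0.38. Adipocyte genes rose in 1 and fell in 3 of 10, likewise over the list alone (median -1.04, adjusted p = 0.700), with the adiponectin gene Adipoq lower (bound -3.09).

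Markers of other tissue compartments and receptors went both ways. Stromal fibroblast genes rose in 7 and fell in 6 of 23, likewise over the list alone (median 0.26, adjusted p = 0.367), with the proteoglycan gene Ogn higher (3.64 ± 0.22) and Thy1 lower (-2.17 ± 0.18). Steroid and nuclear receptors rose in 8 and fell in 8 of 25, likewise over the list alone (median -0.21, mean -0.11, camera direction up, adjusted p = 0.888), with Nrip1, a receptor corepressor, higher (1.82 ± 0.21). Endothelial genes rose in 2 and fell in 9 of 16, likewise over the list alone (median -0.66, adjusted p = 0.324), with Sox7 at 2.06 ± 0.17 and the VEGF receptor gene Kdr at -1.22 ± 0.37. Mesothelial genes rose in 3 and fell in 2 of 10, likewise over the list alone (median 0.30, adjusted p = 0.209), with Wt1 at -2.33 ± 0.37 and Krt19 at 1.72 ± 0.15. Ovary and oocyte genes rose in 3 and fell in 4 of 11, likewise over the list alone (median -0.37, mean 0.55, adjusted p = 0.634), with the germ cell helicase gene Ddx4 at 6.64 ± 0.38. Skeletal muscle genes rose in 2 and fell in 5 of 13, likewise over the list alone (median -0.43, adjusted p = 0.625), with Casq1 at -3.41 ± 0.26, and red blood cell genes fell in 2 of 7 (likewise over the list alone; median -0.09, adjusted p = 0.708), with Hbb-bh1 at -1.57 ± 0.56, a call lost without vehicle replicate 4 (adjusted p = 0.0740) and DES replicates 1, 2 or 3 (adjusted p = 0.0528 to 0.105), with quantile normalization (adjusted p = 0.0994) and after adding 16 to each value (adjusted p = 0.126).

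In all, 8876 of 17145 genes were called with DES in wild type, 3685 higher and 5191 lower, of which 2367 and 2986 changed at least 2-fold. In 7599 of these calls the 4 DES and 4 vehicle arrays did not overlap. This held for 50.5% of all genes, where chance gives 2.86%. Without the doubted arrays the count was 10837, with 4695 higher and 6142 lower. The share of higher calls depended on scaling. It was 41.5% with 75th percentile scaling, with a median of all genes of -0.16, and 56.8% of 8344 calls with median scaling, which placed that median at 0.09.

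**Figure D2:**
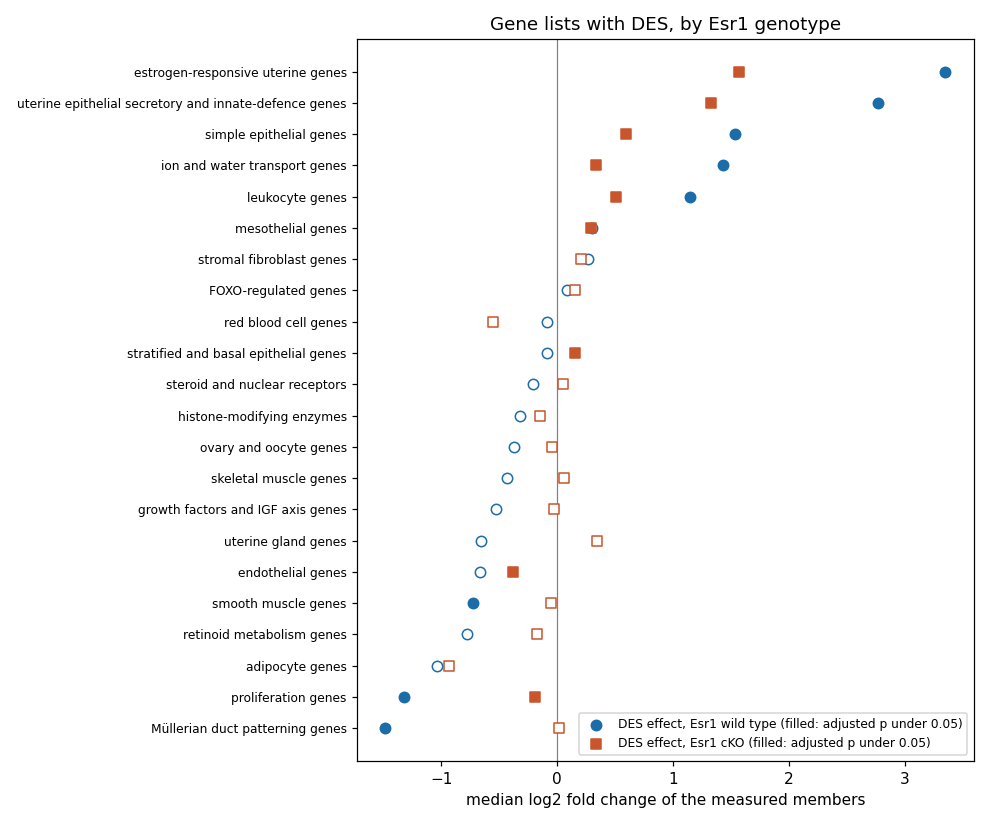
Median log2 fold change with DES of the measured members of 22 gene lists, in Esr1 wild-type (blue circles) and Esr1 cKO uteri (orange squares), with filled symbols for lists called by camera with a preset correlation. The estrogen-responsive list lay at 3.35 in wild type and 1.57 in cKO, and the Müllerian duct patterning list at -1.48 and 0.01.

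In Esr1 cKO uteri, DES raised many of the genes raised in wild type, by smaller amounts. Clca1 rose by 7.22 ± 0.40 (adjusted p = 3.3e-13), Ppp2r2c, a phosphatase regulatory subunit, by 7.01 ± 0.29, Uox by 6.76 ± 0.25, Ltf by 5.77 ± 0.35, and the serpin Serpinb11, dim on all vehicle cKO arrays, by at least 5.92. Qrfpr, a neuropeptide receptor (bound -3.10), and Lce3c, a cornified envelope protein (-4.15 ± 0.43), had the largest fitted falls. Estrogen-responsive genes rose in 16 of 27 with none lower (17 higher and 2 lower adjusted over the list alone; median 1.57, adjusted p = 2.2e-22). Lcn2 (4.88 ± 0.46) and Aqp8 (4.38 ± 0.46) were among them. Secretory and innate-defence genes rose in 13 and fell in 2 of 20, likewise over the list alone (median 1.33, adjusted p = 5.3e-13), with the complement factor Cfb at 2.83 ± 0.20 and the chemokine Cxcl17 at 2.79 ± 0.32. Ion and water transport genes rose in 7 of 23 (9 adjusted over the list alone; median 0.34, adjusted p = 2.1e-07), among them Car12 (3.58 ± 0.35). These 3 lists kept their call with an estimated correlation (adjusted p = 1.5e-06, 2.7e-04 and 5.8e-04).

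Other lists were called in Esr1 cKO with the preset but not the estimated correlation. With fry 8 of the 9 list calls in Esr1 cKO remained, and that of the proliferation list was lost (fry adjusted p = 0.313). Simple epithelial genes rose in 9 and fell in 1 of 24 (14 and 1 adjusted over the list alone; median 0.59, adjusted p = 1.3e-07, and 0.116 with an estimated correlation), with Elf3 at 1.85 ± 0.39 and Cldn6 at -1.84 ± 0.30. Leukocyte genes rose in 9 of 22 (10 adjusted over the list alone; median 0.51, adjusted p = 4.8e-04, and 0.188 with an estimated correlation), led by Itgam (2.38 ± 0.46) and Cd14 (1.65 ± 0.21). Endothelial genes shifted down by a median of -0.38 (adjusted p = 0.0181, and 0.297 with an estimated correlation), with Robo4 lower (-0.84 ± 0.21), Sox7 higher (0.77 ± 0.17, and 0.13 with an adjusted p of 0.741 when its probes were averaged) and 14 of 16 not called (1 and 2 adjusted over the list alone). The proliferation list shifted by only -0.19 (adjusted p = 0.0376, and 0.632 with an estimated correlation), with none of its 29 members called over all genes or over the list alone. Mcm3 had the largest value, -0.40 ± 0.38 (adjusted p = 0.685). Mesothelial genes rose in 3 of 10, likewise over the list alone (median 0.30, adjusted p = 0.0181, and 0.297 with an estimated correlation), and stratified and basal epithelial genes rose in 6 and fell in 1 of 26 (7 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.0453, and 0.297 with an estimated correlation). Krt19, a keratin of simple epithelia and mesothelium, rose by 0.93 ± 0.15, Calml3, a calmodulin-like keratinocyte protein, by 3.78 ± 0.40, and the serpin Serpinb5 by at least 1.57. Without the doubted arrays the calls of the proliferation, mesothelial and stratified lists were lost (adjusted p = 0.0557, 0.0762 and 0.0994).

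The count in Esr1 cKO was 1539 genes, 1096 higher and 443 lower, of which 715 and 214 changed at least 2-fold. The 4 and 4 arrays did not overlap in 1479 of these calls, and in 30.8% of all genes, where chance gives 2.86%. Of the 1539 genes, 1270 were called the same way in wild type, 78 the other way, and 191 were not called there. The 2367 genes raised at least 2-fold in wild type had a median of 1.81 there and 0.46 in cKO, where 770 of them (32.5%) were called higher and 10 lower (camera adjusted p = 1.2e-37). This comparison shares no array with the list. The 2986 genes lowered at least 2-fold had medians of -1.65 and -0.26, and 326 (10.9%) were called lower and 50 higher in cKO (adjusted p = 1.8e-10, and adjusted p = 0.129 with an estimated correlation), or 206 lower without DES cKO replicate 4. Of the lists made without the doubted arrays, 1146 of 2425 raised genes were called higher and 697 of 2880 lowered genes lower. Without those arrays, neither of which is in this comparison, the count rose to 3545 (2011 higher, 1534 lower), since all groups share an estimate of the spread. With only the 8 compared arrays in the fit it was 4304.

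The DES effect differed between Esr1 cKO and wild type at 4687 genes, tested as a difference of differences. For genes such as Serpina9, a serine protease inhibitor (bound -6.26, adjusted p = 4.2e-13), Aoc1 (-7.27 ± 0.62), Mfsd4a, a membrane transporter family member (-6.97 ± 0.57), and Scgb3a1, a secretoglobin (-6.88 ± 0.58), the difference was negative. It was positive for Slc6a2 (at least 6.36), Vwa2 (at least 6.60), Lgr5 (6.72 ± 0.55) and G6pc2 (6.47 ± 0.57), all of which fell in wild type. Of the 2367 raised genes, the difference was called toward a smaller change for 1642 and toward a larger one for 6, and of the 2986 lowered genes for 1978 and 1. These lists and this difference share the wild-type arrays, so the counts are not independent of how the lists were chosen.

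By list, the difference was negative for 19 and positive for 1 of 27 estrogen-responsive genes, likewise over the list alone (median -2.14, adjusted p = 2.2e-12), and negative for 11 and positive for 2 of 20 secretory and defence genes, likewise over the list alone (median -1.80, adjusted p = 6.5e-06). Lcn2 (-6.04 ± 0.66) led both, with Aqp8 (-5.47 ± 0.65) and Sprr2f, a small proline-rich protein (-5.08 ± 0.44), in the first. It was positive for 18 and negative for 1 of 30 Müllerian patterning genes (18 and 2 adjusted over the list alone; median 0.95, adjusted p = 6.3e-05), with Lef1 (4.62 ± 0.47), the hedgehog ligand Ihh (at least 2.65) and Wnt7a (4.01 ± 0.43) highest by fitted value. These calls held with an estimated correlation (adjusted p = 1.7e-04, 0.0176 and 0.0053). With fry all 7 lists called for this difference kept their call. The preset but not the estimated correlation called the proliferation and smooth muscle lists. The proliferation list had 19 of 29 positive (21 adjusted over the list alone) and a median of 1.05, led by E2f1 (1.71 ± 0.39). Its camera adjusted p was 1.6e-06, and 0.361 with an estimated correlation. The smooth muscle list had 8 of 17 positive, likewise over the list alone, and a median of 0.66. Its camera adjusted p was 0.0071, and 0.361 with an estimated correlation. Ldb3 was at 2.88 ± 0.91 and Myocd at 1.67 ± 0.29. The Ldb3 value was -0.04 when its probes were averaged, and its call was lost with quantile normalization (adjusted p = 0.0608). The preset correlation also called the simple epithelial list (14 negative and 2 positive of 24, 16 and 2 adjusted over the list alone, median -0.94, camera adjusted p = 6.3e-05, and 0.295 with an estimated correlation), in which Cldn6 (3.75 ± 0.43) and Ovol1 (3.08 ± 0.56) went the other way, and the ion and water transport list (11 negative and 2 positive of 23, 11 and 3 adjusted over the list alone, median -0.41, camera adjusted p = 0.0258, and 0.174 with an estimated correlation), led by Aqp8 and Car12 (-2.94 ± 0.49). The last call was lost without the doubted arrays (adjusted p = 0.0511). Of the 4687 genes 2642 had a positive and 2045 a negative difference (56.4% positive, and 46.1% with median scaling). The count was 7266 (3945 and 3321) without the doubted arrays.

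Among DES-treated uteri, Esr1 cKO differed from wild type mostly at the same named genes. This comparison is part of the difference of differences above and shares its DES arrays, so that overlap is largely built in. Slc6a2 (at least 6.35), Vwa2 (at least 6.54), G6pc2 (6.57 ± 0.40) and Lgr5 (6.34 ± 0.39, adjusted p = 6.4e-13) were higher in cKO. Aoc1 (-7.41 ± 0.44), Lypd8, an antibacterial surface protein (-6.82 ± 0.61), Mfsd4a (-6.69 ± 0.40), Scgb3a1 (-6.48 ± 0.41) and Pigr (-6.39 ± 0.35, adjusted p = 1.2e-13) were lower. Estrogen-responsive genes were lower in 20 and higher in 3 of 27, likewise over the list alone (median -2.47, adjusted p = 6.5e-16), secretory and defence genes lower in 12 and higher in 1 of 20, likewise over the list alone (median -1.90, adjusted p = 3.1e-07), and ion and water transport genes lower in 12 of 23, with 12 lower and 2 higher adjusted over the list alone (median -0.95, adjusted p = 1.4e-04). Aqp8 (-5.53 ± 0.46), Lcn2 (-5.45 ± 0.46) and Car12 (-2.73 ± 0.35) were among the genes called lower. Müllerian patterning genes were higher in 19 and lower in 1 of 30, likewise over the list alone (median 0.88, adjusted p = 3.1e-07), with Lef1 at 4.42 ± 0.33, Wnt7a at 4.13 ± 0.30, Wnt11 at 3.55 ± 0.33 and the homeobox gene Msx1 at 2.76 ± 0.29. These 4 lists held with an estimated correlation (adjusted p = 2.6e-05, 0.0071, 0.0089 and 4.0e-04). Proliferation genes were higher in 25 of 29 (29 adjusted over the list alone; median 1.08, adjusted p = 5.3e-10, and 0.189 with an estimated correlation), among them Cdc6 (1.45 ± 0.24) and Mcm5 (1.33 ± 0.20), which act in replication licensing. Simple epithelial genes were lower in 18 and higher in 2 of 24, likewise over the list alone (median -1.07, adjusted p = 8.2e-07, and 0.115 with an estimated correlation), and smooth muscle genes higher in 7 of 17, likewise over the list alone (median 0.54, adjusted p = 0.0132, and 0.325 with an estimated correlation), with Cldn6 at 4.06 ± 0.30, Ovol1 at 2.86 ± 0.40, Krt7 at -2.20 ± 0.24 and Myocd at 1.43 ± 0.21. The count was 5224 genes, 2843 higher and 2381 lower in cKO, and in 4841 of them the arrays did not overlap (47.0% of all genes, where chance gives 2.86%). Without the doubted arrays it was 8221 (4488 and 3733). For the test of DES-responsive genes the lists were made from replicates 1 and 2 of the shared wild-type group and tested on its replicates 3 and 4. Raised genes had a median of -0.87 (1172 of 2379 called lower, 5 higher, adjusted p = 1.9e-70) and lowered genes a median of 0.77 (1193 of 2988 called higher, 9 lower, adjusted p = 1.4e-43). The calls in these directions were 1560 of 2499 and 1753 of 2976 without the doubted arrays. Leaving out DES wild-type replicate 3 or 4 left 1 wild-type array in this test, with the spread taken from the other groups. The counts were then 776 and 723 without replicate 3, and 839 and 650 without replicate 4.

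Without DES, the genes that differed between Esr1 cKO and wild type were mostly of low signal, and no list was called. The largest fitted rises in cKO were those of Fpr-rs3, a formyl peptide receptor family member (at least 2.06, adjusted p = 9.2e-08), and the olfactory receptor genes Olfr870 (at least 2.41) and Olfr693 (at least 2.44). The largest fitted falls were those of Fam25c (bound -2.90) and Olfr1366 (bound -1.96). Of the 23 ion and water transport genes 3 were lower, led by the water channel gene Aqp2 (-2.69 ± 0.20, adjusted p = 2.9e-09), likewise over the list alone (median -0.21, adjusted p = 0.652). Stratified and basal epithelial genes were lower in 5 of 26 (5 lower and 2 higher adjusted over the list alone; median -0.41, adjusted p = 0.535), led by Ly6d, a keratinocyte surface protein (-2.83 ± 0.60), whose call was lost with only the 8 compared arrays in the fit (adjusted p = 0.173, and 0.0887 for Fam25c), and Ivl, a cornified envelope precursor (bound -0.64). Estrogen-responsive genes had a median of -0.25 (adjusted p = 0.652), with the trefoil factor gene Tff1 (-2.22 ± 0.48) and Pgr, the progesterone receptor gene (-0.62 ± 0.16, adjusted p = 0.0137), lower, likewise over the list alone. The Pgr call was lost without wild-type replicate 1 or 3 or cKO replicate 2 (adjusted p = 0.0501, 0.0504 and 0.0646). In all 1282 genes were called, 460 higher and 822 lower in cKO, and 1117 of them did not overlap (15.99% of all genes, where chance gives 2.86%). Of the calls 96.6% lay under the median level of the tested genes, against 47.4% to 65.2% in the other comparisons, and 199 of 497 olfactory receptor genes were called. The share higher in cKO was 35.9%, 46.5% with quantile normalization and 24.2% after adding 16 to each value. The count was 1514 (601 and 913) without the doubted arrays and 330 with a filter at the array median. With lists from part of the wild-type arrays, as above, the genes raised by DES had a median of 0.07 (329 of 2241 higher, 68 lower, adjusted p = 7.4e-07) and those lowered by DES -0.35 (438 of 2605 lower, 31 higher, adjusted p = 6.4e-07, and adjusted p = 0.210 with an estimated correlation). Leaving out wild-type replicate 3 or 4, or the doubted arrays, which include replicate 4, left 1 wild-type array in this test, assumed to vary like the other groups. The median of the lowered genes was then -0.14 (88 of 2629 lower) without replicate 4, -0.61 (789 of 2629 lower) with replicate 4 alone and -0.17 (209 of 2839 lower) without the doubted arrays. Of the raised genes 196 were higher and 12 lower without replicate 4, 289 lower with replicate 4 alone, and 308 higher and 28 lower of 2381 without the doubted arrays. Without replicate 1, which only makes the lists, 287 of 1909 lowered genes were lower. With the 200 largest rises in place of the raised list the median was -0.15 (adjusted p = 0.617).

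**Figure D3:**
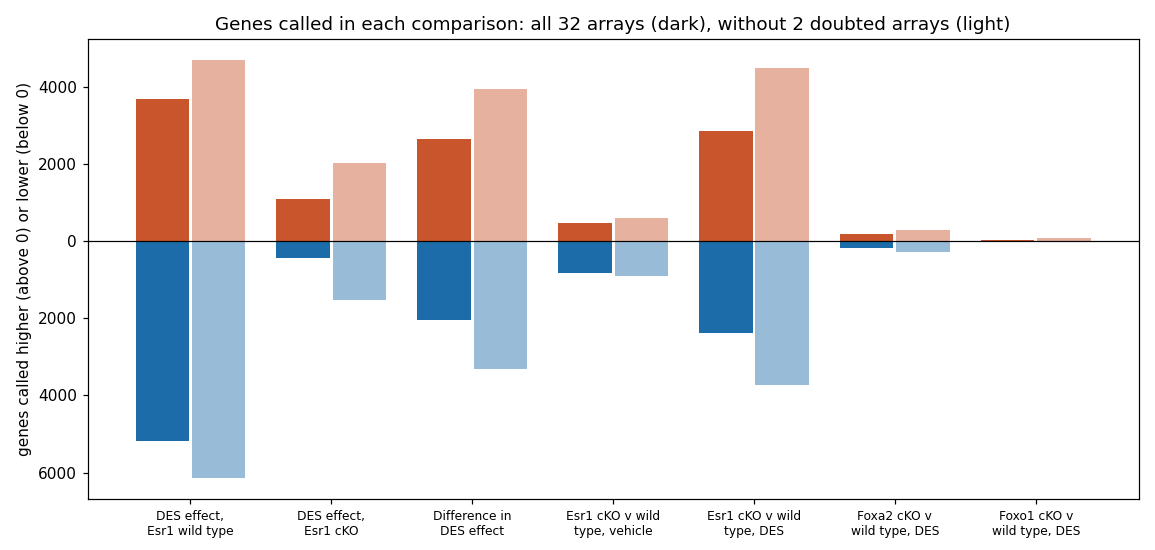
Number of genes called higher (above 0, orange) and lower (below 0, blue) in 7 comparisons, with all 32 arrays (dark bars) and without the doubted arrays (light bars). The DES effect in Esr1 wild type had 8876 calls and the Foxo1 comparison 38.

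Under DES, some genes were lower and others higher in Foxa2 cKO than in wild-type uteri. Besides Foxa2, the largest fitted falls were those of Pla2g10, a secreted phospholipase (-3.07 ± 0.26, adjusted p = 2.4e-08), Agr2, a protein disulfide isomerase of mucus-producing cells (-3.04 ± 0.25, adjusted p = 2.4e-08), and Ces1f, a carboxylesterase (bound -1.999). The largest fitted rises were those of Cuzd1, first described as an estrogen-induced uterine gene (3.69 ± 0.50, adjusted p = 4.5e-05), Ldhc, a lactate dehydrogenase (2.83 ± 0.45), and, after Lhx1os (at least 0.45), Wnt7a (2.39 ± 0.30, adjusted p = 2.1e-05). The transcription factor gene Tfap2c (2.33 ± 0.39), the fatty acid transporter gene Slc27a2 (2.32 ± 0.32) and Il17rb, a cytokine receptor gene (2.24 ± 0.27), also rose. No list was called by camera on all arrays or by fry. With quantile normalization 1 list was called, and without the doubted arrays 1. Of the 14 gland genes 2 fell, likewise over the list alone, Foxa2 itself and the chemokine gene Cxcl15 (-1.498 ± 0.32, adjusted p = 0.0083), while the list had a median of 0.11, a mean of -0.23 and a camera direction down (adjusted p = 0.600). Stratified and basal epithelial genes had Krt14 higher (1.65 ± 0.27) and Krt15 (-1.71 ± 0.25) and Krt4 (-2.05 ± 0.50) lower of 26 (1 and 4 adjusted over the list alone; median -0.16, adjusted p = 0.513). The Krt4 call was lost without wild-type replicate 2 or 3 or cKO replicate 1 or 3 (adjusted p = 0.0511 to 0.0794). Estrogen-responsive genes had 3 of 27 lower, likewise over the list alone, led by Tff1 (-2.36 ± 0.48, adjusted p = 0.005), with a median of 0.04, a mean of -0.06 and a camera direction down (adjusted p = 0.688). The genes raised by DES in the Esr1 line had a median of -0.02 here (100 lower, 72 higher, adjusted p = 0.275) and the lowered genes 0.10 (29 higher, 13 lower, adjusted p = 0.228). Without wild-type replicate 2 both lists passed the test (-0.02 with an adjusted p of 0.0350, and 0.27 with an adjusted p of 0.0032). With the 200 largest rises the median was -0.20 (adjusted p = 3.0e-04), and without the doubted arrays both medians changed sign (0.03 and -0.03). These counts varied with the array left out, from 37 to 122 higher among the raised genes and from 13 to 113 among the lowered genes. In total 379 genes were called, 190 higher and 189 lower. In 299 of them the arrays did not overlap, as in 5.43% of all genes, where chance gives 2.86%. The count was 1057 without wild-type replicate 2, 666 without wild-type replicate 3, 244, 230 and 218 without cKO replicate 2, 3 or 4, and 585 (294 and 291) without the doubted arrays. With only these 8 arrays in the fit it was 9, and Foxa2 itself had an adjusted p of 0.0945. Among the genes named here, Pla2g10, Agr2 and Cuzd1 kept their call there. The call of Lhx1os was also lost without cKO replicate 3 (adjusted p = 0.0602).

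Under DES, several interferon-inducible genes were higher in Foxo1 cKO than in wild-type uteri. The top 8 genes were the chemokine gene Cxcl10 (4.39 ± 0.60, adjusted p = 1.1e-04), the interferon-induced GTPase genes Tgtp1 (4.30 ± 0.41, adjusted p = 3.9e-07), Gbp6 (2.96 ± 0.41), Gbp4 (2.77 ± 0.42), Iigp1 (2.67 ± 0.40) and Igtp (2.62 ± 0.31), Cd274, which encodes PD-L1 (at least 2.02), and Ciita, the class II transactivator gene (at least 1.99). Besides Foxo1, the largest fitted falls were those of Pax1, a paired box factor gene dim on all cKO arrays (bound -0.56), and Aldh1a3, a retinoic acid synthesis gene (-1.80 ± 0.23, adjusted p = 5.5e-05). The FOXO-regulated genes, of which only Foxo1 itself was called among 28 (likewise over the list alone), shifted by a median of -0.06 (camera adjusted p = 0.0179, and 0.399 with an estimated correlation). The deleted gene Foxo1 is a member and adds to this result, and the list was not tested without it, so no shift of the other members can be inferred. Red blood cell genes, markers of blood in the tissue, shifted up by a median of 1.37 over 7 members, none called over all genes and 5 higher adjusted over the list alone (adjusted p = 4.8e-08, and 0.0706 with an estimated correlation). Hba-a1 had the largest value, 1.44 ± 0.42 (adjusted p = 0.327). Secretory and defence genes shifted by 0.31 (none called, 2 higher of 20 over the list alone; adjusted p = 1.4e-04, and 0.0706 with an estimated correlation), with Saa3 at 1.78 ± 0.43 (adjusted p = 0.0952). Leukocyte genes shifted by 0.25 (none called, 1 higher of 22 over the list alone; adjusted p = 0.0263, and 0.399 with an estimated correlation), with the class II gene H2-Ab1 at 0.94 ± 0.25 (adjusted p = 0.166). The smooth muscle (0.21, adjusted p = 0.0263, and 0.399 with an estimated correlation), Müllerian (-0.04, adjusted p = 0.0263, and 0.144) and stromal fibroblast lists (-0.02, adjusted p = 0.0318, and 0.366) also passed the preset test, with no member called over all genes or over the list alone. Genes raised by DES in the Esr1 line had a median of 0.13 (12 higher, 2 lower, adjusted p = 3.7e-04, and adjusted p = 0.0701 with an estimated correlation), which was -0.04 with median scaling, against a median of all genes of 0.05 and -0.10. It was 0.10 (adjusted p = 0.143) without cKO replicate 4. Genes lowered by DES had a median of 0.09 (adjusted p = 0.803), and 0.16 (adjusted p = 0.0159) without cKO replicate 4.

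**Figure D4:**
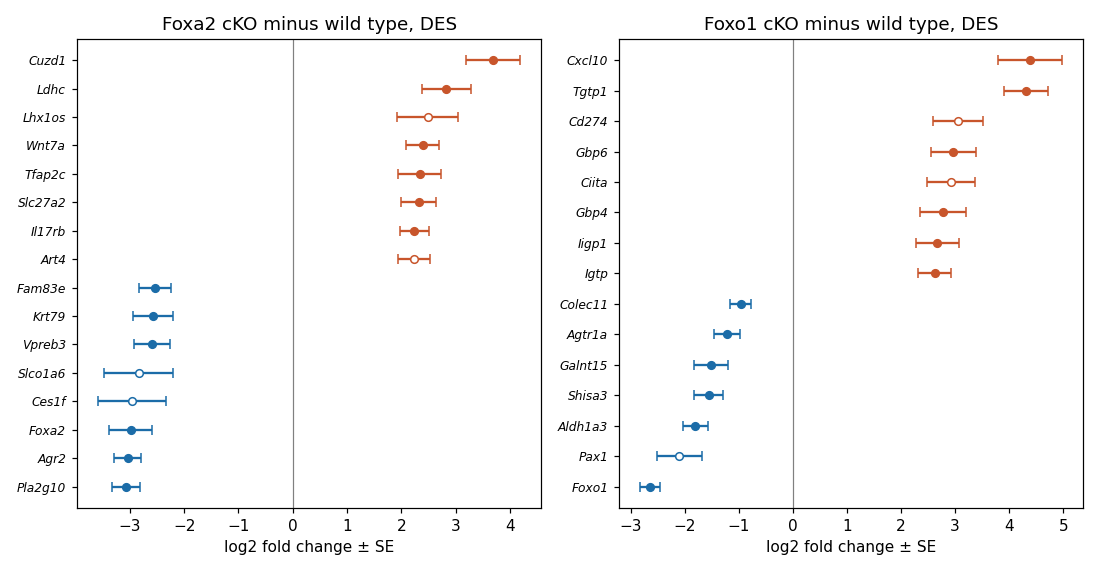
Log2 fold change ± SE, cKO minus wild type under DES, of the genes with the largest changes after Foxa2 deletion (left) and Foxo1 deletion (right), with open symbols where one group was dim on all 4 arrays, so that the fold itself is only a bound. Tgtp1 lay at 4.30 ± 0.41 and Pla2g10 at -3.07 ± 0.26.

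The Foxo1 comparison called 38 genes, 31 higher and 7 lower. At an unadjusted limma p under 0.05 there were 648 of 17145 genes. This is under the share of 0.05 that chance gives on average, so it does not point to further changed genes. In all 38 calls the arrays did not overlap, as in 8.09% of all genes, where chance gives 2.86%. On simulated data for this comparison the test recovered 48.8% of genes changed by 1 on the log2 scale and 88.8% of those changed by 2. Those data were independent between genes and held neither deviating arrays nor a division between replicates, so real recovery may differ. The share higher was 81.6%, 60.3% of 63 calls with quantile normalization and 53.8% of 39 with median scaling. The count was 24 without wild-type replicate 3, 25 without cKO replicate 1, and 111 (81 and 30) without the doubted arrays. Arrays 1 and 2 of both Foxo1 groups stood apart from arrays 3 and 4. The count was 43 with this division as a block, 21 within replicates 1 and 2 and 39 within replicates 3 and 4. Pax1 lost its call without 5 of the 8 arrays in turn (adjusted p = 0.0589 to 0.109), after adding 16 to each value (-0.84, adjusted p = 0.982), and within replicates 1 and 2 or 3 and 4 (adjusted p = 0.171 and 0.483). Aldh1a3 lost it when its probes were averaged (adjusted p = 0.334) and within replicates 1 and 2 (adjusted p = 0.124). With only these 8 arrays in the fit, Pax1, Cd274 and Ciita missed the threshold (adjusted p = 0.0769, 0.0855 and 0.112).

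The effects of Foxo1 and Foxa2 deletion differed at 164 genes, tested as a difference of differences, 102 with a positive and 62 with a negative value of the Foxo1 minus the Foxa2 effect. Foxa2 (3.26 ± 0.57, adjusted p = 0.0021) and Foxo1 (-2.44 ± 0.26, adjusted p = 4.5e-06) were among them. Esr1 was not called after Foxa2 (-0.93 ± 0.40, adjusted p = 0.233, and -0.21 without wild-type replicate 1) or Foxo1 deletion (0.07 ± 0.40, adjusted p = 1.00). The positive share was 62.2%, 49.7% with quantile normalization and 41.0% with median scaling. The count was 96 without Foxa2 cKO replicate 4, 107 and 96 without Foxo1 wild-type replicate 1 or 3, 104 without Foxo1 cKO replicate 3, and 458 (266 and 192) without the doubted arrays.

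The wild-type DES groups of the 3 lines, which share the label wild type and the treatment, also differed from each other. The Foxa2 line differed from the Esr1 line at 6048 genes, the Foxo1 line from the Esr1 line at 6029, and the Foxo1 line from the Foxa2 line at 2832. Without the doubted arrays the counts were 8515, 9543 and 3436. In the last of these the count was 5337 without Foxa2 wild-type replicate 2, 1808 without Foxo1 wild-type replicate 1 and 1884 without Foxo1 wild-type replicate 2. The share higher than in the Esr1 line was 70.4% for the Foxa2 line and 70.9% for the Foxo1 line, with a median of all genes of 0.18 in both. It was 47.7% and 53.6% with quantile normalization and 57.4% and 53.5% with median scaling. Line, genetic background, litter and array batch cannot be told apart in these groups, so cKO effects were compared with the wild type of the same line.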

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

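The tests of a single deviating array, of signal near the floor, of the sign of brighter genes, of an even share of cells that kept Esr1, of compressed bright signals and without the doubted arrays were chosen after the results were seen, and for the other tests the plan or the prediction came before the result. In 8 of 56 sets of 4 values, which are several measures in each of the 8 groups, 1 array lay far from the other 3. Chance alone gives about 1 in 20 independent sets, but these sets share arrays, so that rate is only a guide. The 75th percentile of replicate 1 of the DES-treated Foxa2 wild-type group was 9024, and its mean correlation with the others of its group was 0.907 (others 0.956 to 0.964). On the same array the levels of Esr1 (5.00, others 2.02 to 2.25) and Foxo1 (4.93, others 3.60 to 3.78) were apart. The mean correlation of replicate 4 of the vehicle-treated Esr1 wild-type group was 0.940 (others 0.971 to 0.975). In the DES-treated Foxa2 cKO group the 75th percentile of replicate 1 was 1389.6 (others 891 to 946) and the Foxa2 level of replicate 2 was 0.36 (others -0.29 to -0.24). The Foxa2 level of replicate 4 of the DES-treated Foxo1 cKO group was 3.22 (others 2.94 to 2.96). The array with the high Esr1 level belongs to a wild-type group, and no exchange of labels was tested.

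The difference between groups stood out for 4687 genes in the DES effect (Esr1 cKO minus wild type) and for 164 genes between the Foxo1 and Foxa2 deletion effects. None of the other 99 of 100 drawn splits gave as many in either case (1 of 100 each, the real one, with at most 3372 and 74 in the others). This makes chance less likely but, without adjustment over the comparisons, does not exclude it. For the 164 genes a further limit is that another split of the Foxa2 arrays alone gave more calls than the real one. Among the targeted genes, Foxa2 differed in the DES effect by -3.33 (-3.83 to -0.77 over its 10 probes, with a vehicle signal near the floor). Between the forkhead deletions Foxa2 differed by 3.26 and Foxo1 by -2.44. Outside the gene tests, 3401 of 7247 tested probes without a gene symbol were called with DES in wild type (46.9%, against 51.2% with a symbol).

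Part of the DES response remained in Esr1 cKO uteri. If a fixed share of cells had kept Esr1, each gene would keep the same fraction of its wild-type rise. The prediction was that differences in that fraction would then not repeat. It was examined over 233 genes that rose by at least 3 on the log2 scale in wild type, with neither low nor very bright levels there. The fraction repeated between replicates 1 and 2 and replicates 3 and 4 (rank correlation 0.864). The median kept was 10.6% (interquartile range 4.73 to 18.6), with Slc7a11 (87.0%) and Shisa2 (60.9%) highest. A probe background that is the same on each array largely cancels in this fraction, since the vehicle level is subtracted. A nonlinear signal of a probe would repeat as well and was not tested. The repeated spread thus argues against an even share for these genes, as far as their signal is linear. The kept percentage holds for these strongly raised genes, not for the whole response. Compression of bright signals is argued against by the dimmer genes, which kept 9.03% in the lower of both sets. An uneven share between cell types or a pathway without Esr1 may account for the remaining response, and neither was tested.

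Vehicle-treated Esr1 cKO and wild-type uteri differed in many low-signal genes. A single deviating wild-type array as the cause is argued against, since 74.9% of the calls were still called without replicate 4 (960 of 1282, with 1006 in total). Of the calls 96.6% lay under the median level, which is consistent with signal near the floor. The same sign on the DES-treated arrays was seen for 30.4% of the calls and 49.0% of uncalled genes. By the prediction fixed before the result, such shares spoke against Esr1 deletion. The share was also no higher, at 47.7%, among the 44 calls above the median level. Over all calls, opposite signs were more frequent than among uncalled genes, and the cause of this was not tested. Scaling, on which the share higher in cKO depended, is among the untested causes. Signs of genes near the floor cannot be relied on, so the planned test could not decide for most calls. An effect of Esr1 deletion was thus not seen in this test but stays open for the calls near the floor. So does a difference in litter or array handling, which was not tested.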

How the results depend on the processing

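The tests without the doubted arrays and within replicates 1 and 2 or 3 and 4 of the Foxa2 and Foxo1 lines were chosen after the results were seen, and the other alternatives were planned. Signal near the floor limits the changes of named genes that were dim on all 4 arrays of a group, which are given as bounds. With no filter, another variance model (trend and robust) or the division of the lines as a block, each named gene kept its direction and its side of the threshold, and with the array weights no named gene lost its call. Of 1648 values of named genes with 1 array left out, 1623 kept both, 21 lost and 4 gained a call, and no called gene changed direction. With only the compared groups in the fit, 156 of 180 kept both, 21 lost and 3 gained a call. The cause was not tested for the following changes except where given. With quantile normalization the Foxo1 comparison had 63 calls (38 higher, 25 lower). With a filter at the array median the comparison of vehicle-treated Esr1 genotypes had 330, with fewer dim genes tested. With all probes as the unit, more of which are tested, counts were 18451 for the DES effect in Esr1 wild type, 2870 in cKO, 8466 for their difference, 2659 and 9268 for the Esr1 genotypes without and with DES, and 88 for Foxo1. With only the compared groups in the fit they were 4304 for DES in Esr1 cKO, 8411 for the Esr1 genotypes with DES, 9 for Foxa2 (1 higher, 8 lower) and 80 for the difference of Foxo1 and Foxa2. With array weights they were 5487 for DES in Esr1 cKO, 8377 for the difference in the DES effect, 2114 and 8986 for the Esr1 genotypes without and with DES, 2918 for Foxa2, 419 for Foxo1 and 1987 for their difference, and 10012, 10412 and 8398 for the wild-type groups (Foxa2 against Esr1 line, Foxo1 against Esr1 line, Foxo1 against Foxa2 line). A 2-fold minimum left 5353 for DES in wild type, 929 in cKO, 2648 for the Esr1 genotypes with DES and 219 for Foxa2. An adjusted p under 0.01 left 950 for DES in Esr1 cKO, 2791 for the difference, 815 for the vehicle-treated genotypes, 166 for Foxa2, 24 for Foxo1 and 62 for their difference. Without the doubted arrays the counts were 3545 for DES in Esr1 cKO, 7266 for the difference, 8221 for the Esr1 genotypes with DES, 585 for Foxa2, 111 for Foxo1, 458 for their difference and 9543 for the Foxo1 against the Esr1 line. Within replicates 1 and 2 there were 21 calls for Foxo1 and 63 for the difference of the deletions, and within replicates 3 and 4 there were 225 for Foxa2. Ldb3 turned to -0.043 in the difference of DES effects with the mean of its probes. With an estimated correlation 14 of 38 list calls remained. With fry 30 of the 38 remained, none of them in the Foxo1 comparison.

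With 1 array left out, counts ranged from 218 (without cKO replicate 4) to 1057 (without wild-type replicate 2) for Foxa2, from 24 (without wild-type replicate 3) to 46 for Foxo1, from 96 (without Foxa2 cKO replicate 4) to 222 for their difference, and from 1808 (without Foxo1 wild-type replicate 1) to 5337 (without Foxa2 wild-type replicate 2) for the wild types of those lines. The other comparisons stayed within 1.5 times of their counts. Genes raised by DES had a median in Foxa2 cKO of 0.0025 with no fold minimum, -0.20 with the 200 largest rises, 0.038 with quantile normalization, 0.031 without the doubted arrays, and -0.057 to 0.047 with 1 array left out (-0.025, adjusted p = 0.0350, without wild-type replicate 2), and genes lowered by DES -0.026 without the doubted arrays and -0.04 to 0.27 (adjusted p = 0.0032 likewise). In Foxo1 cKO the raised genes had -0.040 with median scaling, 0.13 (adjusted p = 0.0701) with an estimated correlation and 0.089 to 0.17 with 1 array left out, and the lowered genes -0.021 with quantile normalization, -0.026 with median scaling and 0.047 to 0.16 with 1 array left out. In vehicle-treated uteri the raised genes had -0.15 with the 200 largest rises. With an estimated correlation the lowered genes kept -0.26 (adjusted p = 0.129) in Esr1 cKO with DES and -0.35 (adjusted p = 0.210) in vehicle-treated Esr1 cKO. Replicate number as a block gave between 36 calls for Foxo1 and 9237 for DES in Esr1 wild type, 556 for Foxa2 and 39 list calls. Arrays were closest to the array of their own number in 0 to 4 of 8 cases, which gave no clear pairing. The mean correlation of deviations between same-numbered arrays was 0.15 for Foxa2 (other numbers -0.03) and 0.09 for Foxo1 (other numbers -0.03). For the DES-treated Esr1 genotypes it was -0.17 (other numbers 0.06). Structure shared by replicate number in the forkhead lines thus stays possible.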

Other observations

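The tests of Ifi202b, of Cdh1 between the lines, of interferon-inducible genes, whose lists were added after the data were seen, and of leukocytes in the tissue were chosen after the results were seen, and the retinoid, growth factor and histone enzyme lists and the splits were planned. DES also changed single genes of retinoid metabolism in Esr1 wild-type uteri. Dhrs9, a retinol dehydrogenase gene, rose by 6.43 ± 0.63 and Lrat, which esterifies retinol, by 5.10 ± 0.31, while Crabp1, a retinoic acid binding protein gene (-5.84 ± 0.42), and Cyp26b1, which degrades retinoic acid (-3.84 ± 0.44), fell. Of the 15 retinoid metabolism genes 5 rose and 8 fell (5 and 8 adjusted over the list alone), and the list was not called (median -0.78, adjusted p = 0.383). Among growth factors and IGF axis genes, 6 rose and 15 fell of 29 (6 and 15 adjusted over the list alone; median -0.53, adjusted p = 0.383), with the activin subunit gene Inhbb at 5.40 ± 0.18 and the EGF receptor ligand gene Ereg higher (at least 1.25). Histone-modifying enzymes rose in 2 and fell in 10 of 29 (2 and 10 adjusted over the list alone; median -0.32, adjusted p = 0.171), with Hdac9 at -1.53 ± 0.36 and the polycomb gene Ezh2 at -1.31 ± 0.16. In Esr1 cKO, Dhrs9 rose by 3.66 ± 0.63, Inhbb by 2.54 ± 0.18, and Crabp1 fell by 2.53 ± 0.42.

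The wild-type groups of the lines differed in single genes by very large amounts. Ifi202b, an interferon-inducible gene known to vary between mouse strains, was dim in the Esr1 wild type (-8.78 to -8.23) and at 0.90 ± 0.95 (SD, n = 4) in the Foxa2 and 1.76 ± 0.08 in the Foxo1 wild type. Its arrays in Foxa2 cKO ranged from -7.07 to 0.82 (adjusted p = 0.0753 against wild type), so the arrays of this group differed among themselves. It was called without cKO replicate 2 or 3, with array weights or with replicate number as a block (adjusted p = 0.0093, 0.0107, 0.0161 and 0.0334). The change ranged from -5.07 without cKO replicate 2 to -2.44 without cKO replicate 1. Cdh1, which encodes E-cadherin, was at 1.16 ± 0.54 (SD, n = 4; 0.67 to 1.73) in the Foxo1 wild type, 3.40 ± 0.71 (2.75 to 4.11) in the Foxo1 cKO and 4.07 ± 0.05 in the Esr1 wild type. It was called higher in Foxo1 cKO (2.24 ± 0.38, adjusted p = 0.0029) and lower in the Foxo1 than in the Esr1 wild type (-2.91 ± 0.38, adjusted p = 1.1e-06). The Foxo1 cKO call was lost with only the compared groups in the fit (adjusted p = 0.0703) and within replicates 1 and 2 (adjusted p = 0.222). The other 23 simple epithelial genes had a median of 0.12 in Foxo1 cKO and -7.0e-04 between the wild types, without a comparable difference.

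Interferon-inducible genes were higher in Foxo1 cKO uteri. A second list without the named genes had 26 of 28 measured, all positive and 10 called higher (median 0.84). The mean of this list was above all wild-type arrays on 4 of 4 cKO arrays. It exceeded the wild-type mean by 1.12 to 1.23 on cKO replicates 1 to 3 and by 0.51 on replicate 4. The rise was thus uneven but not confined to a single animal. The list was added after the data were seen and 10 of its members are calls on the same arrays, so this was largely fixed in advance. The list rose within replicates 1 and 2 and within replicates 3 and 4, by a median of 0.80 in the lower. That division was read from these data and the labels give no batch, so another batch stays untested. The median difference from Foxa2 deletion was 0.85 for the second list, which is consistent with a link to Foxo1 deletion, but a type I interferon list had medians close to each other after Foxo1 and Foxa2 deletion (0.60 and 0.51, with 2 and 3 of 19 called, and camera p = 0.0546 for Foxa2 with an estimated correlation) and the named genes a median of 0.60 after Foxa2 deletion (2 called, camera p = 0.172 likewise), so whether the whole rise is specific to Foxo1 stays open. The leukocyte list without class II genes changed by 0.24, between the bounds set for leukocytes in the tissue and for none, so immune cells and a response of uterine cells could not be told apart, and litter stays untested. Red blood cell genes had a median of 1.37 in the same comparison (camera adjusted p = 0.0706 with an estimated correlation), and blood in the tissue was not tested as a cause.

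Other splits of the arrays were examined for each comparison. With 35 splits the smallest possible share is 1 of 35, here not adjusted over the comparisons, so this test cannot exclude chance by itself. The real split alone gave as many calls for the DES effect in Esr1 wild type (8876, highest other 1691) and cKO (1539, 25). It also stood alone for Esr1 cKO against wild type without DES (1282, 27) and with DES (5224, 5), and for Foxo1 (38, 12). The same held for the wild-type groups, Foxa2 line against Esr1 line (6048, 2937), Foxo1 line against Esr1 line (6029, 9) and Foxo1 line against Foxa2 line (2832, 1195). For Foxa2 the real split did not stand alone, since 2 of 35 splits gave as many calls (379, highest other 1997). The other split parts wild-type replicates 1, 3 and 4 with cKO replicate 1 from wild-type replicate 2 with cKO replicates 2 to 4, which points to a structure of the arrays, although the Foxa2 level itself separates all arrays by genotype.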
